A study of Homo sapiens with 8 samples.

How the data were processed

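Binding of the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in T HESC cells, an established line of human endometrial stromal fibroblasts (ATCC CRL-4003). Per the labels' protocols, the cells were made to decidualize, that is to take on the secretory state of the stroma of early pregnancy, for 2 days with 0.5 mM 8-Br-cAMP and 0.5 µM medroxyprogesterone acetate, a synthetic progestin. They then received L-kynurenine, a tryptophan metabolite that activates AHR, at 100 µM for 1 hour, or stayed in decidualization medium. Chromatin was fixed with 1% formaldehyde for 9 minutes, sheared to between 200 and 600 bp and, after immunoprecipitation with antibody H-211, sequenced with a read length of 75 bp, per the labels' protocols. There were 8 libraries in 4 groups of 2: AHR ChIP and input DNA, each from control and from kynurenine-treated cells. The sample titles gave the group and the replicate letter, A or B.

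The submitters' processing notes name CASAVA 1.4, FastQC, Bowtie2, SAMtools and MACS2 and the builds hg19 and GRCh37, without saying what each was used for. The options of the peak caller are not stated in the sources used here. The names of the peak lists hold abbreviations that may stand for settings, which were not interpreted. Per the labels, the ChIP and input libraries of both replicates of a treatment belong to 1 peak list, so the data used here were 2 lists, each made from replicates A and B together. Each list has no header and 5 columns, which hold the chromosome, start, end, a numbered peak name and a score. The score per peak was given by the authors as a whole number of at least 40. Whether it encodes a p-value or a q-value is not stated, so scores were ranked and compared only between regions of the same list. Limits on the score, applied to both lists, were used as alternatives. Read counts, fold enrichments, summits and values per replicate were not available to this work, so sequencing depth is unknown and no interval for the height of a peak can be given. Intervals were read as BED intervals and are printed with a start counted from 1.

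Several lines of a list can describe the same interval under names that differ by a letter. Lines with identical chromosome, start and end were joined to 1 region, which kept the highest score. Regions of the 2 lists counted as shared when they had at least 1 bp in common. The number of shared regions was set against 1000 random placements of the kynurenine regions, each on its own chromosome between the first and the last region of either list (permutation test, one-sided for more sharing). Assembly gaps could not be left out of these placements. Random placement was also used for the number of kynurenine regions near a control region, with overlapping regions left out of the observed and the random numbers. Crowding was the percentage of regions with another region of the same list within 10 kb, and windows of 1 Mb with at least 10 regions of a list were called dense. Loci were made by joining regions of a list less than 100 kb apart. Shares are given with 95% Wilson intervals, and the lists were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 24 chromosomes. Scores of shared and other regions were compared by enumerating all pairs of regions (exact permutation test of the difference in medians, two-sided), and scores of crowded and other regions by 100000 resamples. Where more than 2 regions counted as shared, a smaller number of random resamples took the place of the enumeration. In all of these tests the unit is the region. Neighbouring regions are not independent, so Fisher's p-values are too small and Wilson intervals too narrow where regions are crowded. A treatment has only 1 list, so the p-values and intervals compare these 2 lists and do not measure the spread between cultures.

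The calculation of the overlap test was checked on simulated lists of the real lengths. Planted regions were set onto control regions, and unrelated lists were placed by the random rule of the test itself. The check therefore does not give the error rate for lists that crowd into the same stretches. It found 5, 50 and 200 of 5, 50 and 200 planted overlaps between 1334 control and 852 kynurenine regions, and 3% of 100 unrelated simulated lists gave a p-value under 0.05. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

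The comparisons of list size, sharing, scores and location relative to genes, the gene lists, the motifs and some of the alternatives were set before the data were examined. The rule for named items was the 10 highest-ranked peaks among control-only, kynurenine-only and shared peaks, ranked by −log10 q, each with its nearest gene, together with members of the fixed gene lists near a peak. The deposited score took the place of the q-value and of the fold enrichment in this rule and in the score comparison, and peak midpoints took the place of summits. Nearest genes, promoters and introns, gene lists, sequence motifs and the AHR target and decidualization genes named in the rule were not analysed here, because the gene table used here describes GRCh38 and no hg19 annotation or genome sequence was used. The builds were compared first: 48 control and 21 kynurenine regions end beyond the last gene of their chromosome in the GRCh38 table, among them the control region at 59014656 to 59014906 on chromosome Y. No coordinates were moved between builds. The shares per chromosome and the nearness of regions without overlap were not among the comparisons set beforehand. The division into crowded and other regions, loci, dense windows and limits on the score were added after seeing the data. So were the displacements, the distance between midpoints and the random thinning. Alternatives covered the score limit, the definition of sharing, the random placement, lists of equal length, the removal of chromosome Y and the removal of crowded or dense parts.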

Results

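AHR occupancy was mapped in decidualized human endometrial stromal cells with and without 1 hour of 100 µM L-kynurenine, to find where the receptor binds in the decidual state and after ligand. Each treatment was represented by 2 ChIP libraries and 2 input libraries, merged by the authors into 1 peak list per treatment. The control list held 1448 lines, which described 1334 distinct regions. The kynurenine list held 882 lines, which described 852 distinct regions. Both lists reached all 24 chromosomes, including Y. Endometrial cells are of female origin, so regions on chromosome Y cannot be read as AHR bound to that chromosome. Where the reads of these regions came from was not tested. Control regions covered 277 kb in total with a median width of 179 bp (range 146 to 1577 bp), and kynurenine regions covered 156 kb with a median width of 168 bp (range 146 to 709 bp). The median score was 70 in the control list (quartiles 58 and 105, highest 359) and 56 in the kynurenine list (quartiles 46 and 67, highest 315). Scores of lists called separately depend on the depth of each, which is unknown, so this difference was not tested. There is no replicate check on any difference between the lists. Nor was a motif or target-gene check made, so a region is a called peak rather than an established AHR site.

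The first comparison asked whether the AHR peak lists of control and kynurenine-treated cells held the same regions. Only 2 regions were shared under the definition of at least 1 bp in common, and both were isolated and ranked high in the kynurenine list. The first lay on chromosome 2 (hg19), where the control region spanned 178128138 to 178128366 and the kynurenine region 178128148 to 178128429, with 219 bp in common. It had the highest score of all 852 kynurenine regions (315) and rank 81 among control regions (164). The second lay on chromosome 8, where the control region spanned 11373415 to 11373587 and the kynurenine region 11373420 to 11373623, with 168 bp in common. It ranked 5 in the kynurenine list (167) and 46 in the control list (193). The nearest other control region was 3126 kb away for the chromosome 2 site and 1872 kb away for the chromosome 8 site. The genes at these positions were not analysed here.

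The shared regions made up 0.150% of control regions (95% Wilson interval 0.0411% to 0.545%) and 0.235% of kynurenine regions (0.0644% to 0.852%). Random placement of the kynurenine regions on their own chromosomes gave 0.184 shared regions on average, and 2 or more in few placements (permutation p = 0.022, one-sided). This difference was lost when each kynurenine region was moved by at most 500 kb from its own place, which gave 1.30 shared regions on average (permutation p = 0.37). With smaller displacements chance exceeded the 2 observed, at 2.79 shared regions within 50 kb (permutation p = 0.77) and 3.41 within 10 kb (permutation p = 0.86). The difference was not lost under displacements of at most 500 kb among regions without a neighbour of their own list within 100 kb, a set chosen after both shared regions were seen to belong to it (2 against 0.055, permutation p = 0.0010, the smallest that 1000 placements can give).

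Shared regions scored higher than the others in both lists. In the kynurenine list the median score was 241 for the 2 shared regions and 56 for the other 850, a difference of 185 (exact permutation p = 1.1e-05, two-sided). In the control list the medians were 178.5 and 70, a difference of 108.5 (exact permutation p = 0.018). Each of these differences rests on 2 regions. Counting regions within 500 bp of each other as shared raised the number of shared control regions to 5 and lowered the control difference to 21 (permutation p = 0.24). The kynurenine difference fell to 76, with 4 shared regions (permutation p = 1.0e-04).

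**Figure D1:**
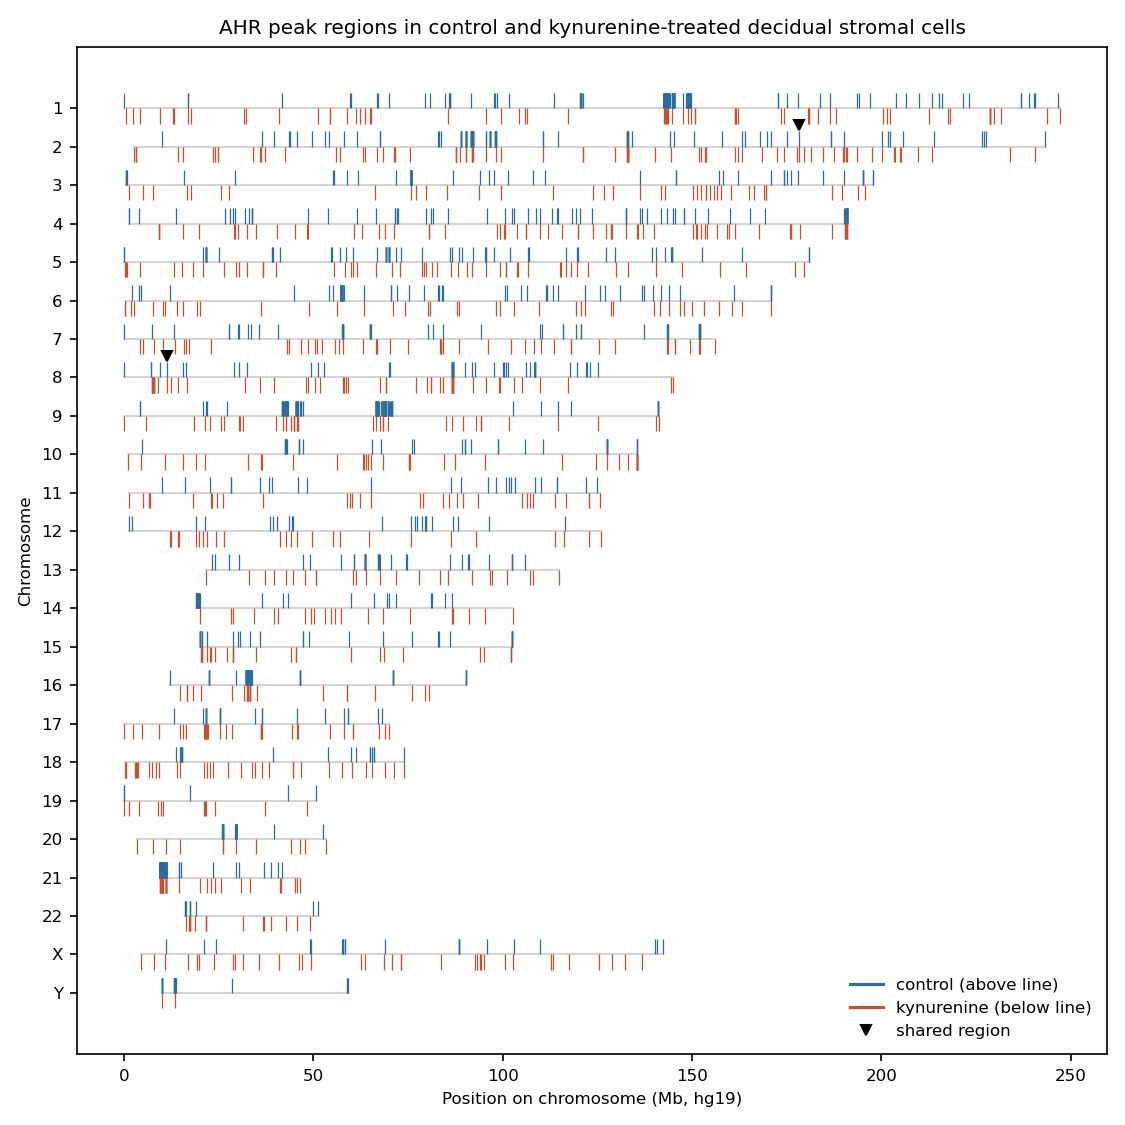
Positions of the 1334 control regions (blue ticks above each line) and 852 kynurenine regions (red ticks below) along the chromosomes in Mb on hg19, with triangles at the 2 shared regions. Each grey line runs from the first to the last region of either list. Control regions form thick bars on chromosomes 1, 9, 16 and 21, while kynurenine regions are spread more evenly.

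The surroundings of the regions with the highest scores were described without a test. Of the 10 control-only regions with the highest scores, 9 lay in windows of 1 Mb with at least 10 control regions and had another control region within 10 kb. The highest was on chromosome 20 at 29638363 to 29638599 (score 359), followed by chromosome 1 at 143539950 to 143540517 (353) and chromosome 21 at 10113510 to 10113821 (320) and 10134768 to 10134969 (317). Others lay on chromosome 9 at 68404896 to 68405208 (308), chromosome 21 at 9459871 to 9460142 (280), chromosome 1 at 143540979 to 143541184 (274) and 143516530 to 143516828 (267), and chromosome Y at 13420701 to 13421062 (263). The exception was the region on chromosome 5 at 95633703 to 95633930 (299), whose nearest control neighbour was 63.7 kb away. Of the 10 kynurenine-only regions with the highest scores, 1 had another kynurenine region within 10 kb, on chromosome 8 at 86747431 to 86747970 (score 128). The highest kynurenine-only region was on chromosome 2 at 121279738 to 121279952 (233), 6805 kb from the nearest control region. It was followed by chromosome 21 at 11026710 to 11026871 (197), chromosome 5 at 373893 to 374081 (174) and chromosome 2 at 87623700 to 87623968 (154). The chromosome 5 region was 272 kb from the nearest control region. Further kynurenine-only regions among these 10 lay on chromosome 20 at 29627356 to 29627516 (121), chromosome 7 at 57871556 to 57871737 (117), chromosome 10 at 127576810 to 127576969 (115), chromosome 8 at 144940440 to 144940619 (112) and chromosome 2 at 132718222 to 132718376 (111). Some of these 10 lay close to control regions: the nearest was 0.531 kb away on chromosome 20, 1.06 kb on chromosome 10, 4.04 kb on chromosome 8 at 86747431 and 6.1 kb on chromosome 21. Those on chromosomes 20 and 21 and the chromosome 8 region at 86747431 lay in windows with at least 10 control regions, and the chromosome 20 region shared its window with the highest control-only region.

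The second comparison asked how the regions were arranged along the genome in each treatment. Control regions had close neighbours of their own list more often than kynurenine regions did. Another control region lay within 10 kb of 707 control regions, or 53.0% (95% Wilson interval 50.3% to 55.7%). In the kynurenine list this held for 72 regions, or 8.45% (6.76% to 10.5%). The difference was 44.5 percentage points (Fisher's exact p = 2.0e-112). This p-value, like the others on crowding, counts neighbours as independent although each makes the other crowded, so it is too small. Random placement gave 1.65% for the control list (highest of 200 placements 2.85%) and 0.665% for the kynurenine list (highest 1.88%), so both lists were more crowded than random placement. When regions less than 100 kb apart were joined, the control list came to 581 loci and the kynurenine list to 746. Of these, 455 control and 690 kynurenine loci held only 1 region, a smaller contrast than that between regions. Of the control regions, 487 lay in 22 loci with at least 10 regions each.

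The control loci with the most regions were on chromosomes 1 and 21. A stretch of 421 kb on chromosome 1 (142545865 to 142967011) held 62 control regions and 2 kynurenine regions, and a stretch of 390 kb farther along (143151438 to 143541184) held 41 and 3. Chromosome 21 had 40 control and 4 kynurenine regions between 9415410 and 9765596, and 39 and 7 between 9896795 and 10195823. A stretch of 330 kb on chromosome 6 (57245873 to 57576088) held 36 control regions and no kynurenine region. However, 3 kynurenine peak numbers are absent between 56111572 and 63277338, which encloses this stretch. Kynurenine peaks removed from it are therefore not excluded. A stretch of 543 kb on chromosome 16 (32308606 to 32851580) held 30 and 6. Kynurenine numbers are absent in other named stretches too. On chromosome 1, 1 is absent between 142697280 and 142842958 and 2 between 143192936 and 143388644. Chromosome 21 lacks 3 between 9556578 and 9714268 and 4 between 9714463 and 9853301, and chromosome 16 lacks 2 between 32755849 and 33293806. Some of these runs reach past the stretch they meet. Removed kynurenine peaks are therefore not excluded there either. In all, 23 windows of 1 Mb held at least 10 control regions. They contained 577 control regions, or 43.3% (95% Wilson interval 40.6% to 45.9%), and 68 kynurenine regions, or 7.98% (6.34% to 10.0%). Outside these windows, 212 of 757 control regions (28.0%) and 47 of 784 kynurenine regions (5.99%) still had a neighbour within 10 kb, a difference of 22.0 percentage points (Fisher's exact p = 2.2e-32). Only 1 window held at least 10 kynurenine regions, on chromosome 8 between 86000001 and 87000000, with 10 kynurenine and 17 control regions. Within it, 10 kynurenine regions spanned 23.6 kb (86726490 to 86750042), and the 6 control regions inside that span shared no base with them.

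Crowded control regions also scored higher than the rest. The median score was 92 for the 707 control regions with a neighbour within 10 kb and 58 for the other 627 (permutation p = 1.0e-05, the smallest that 100000 resamples can give). In the kynurenine list the medians were 61 for 72 regions and 56 for 780, a difference that did not pass the threshold (permutation p = 0.066). Whether the 2 lists differed in this respect was not tested.

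**Figure D2:**
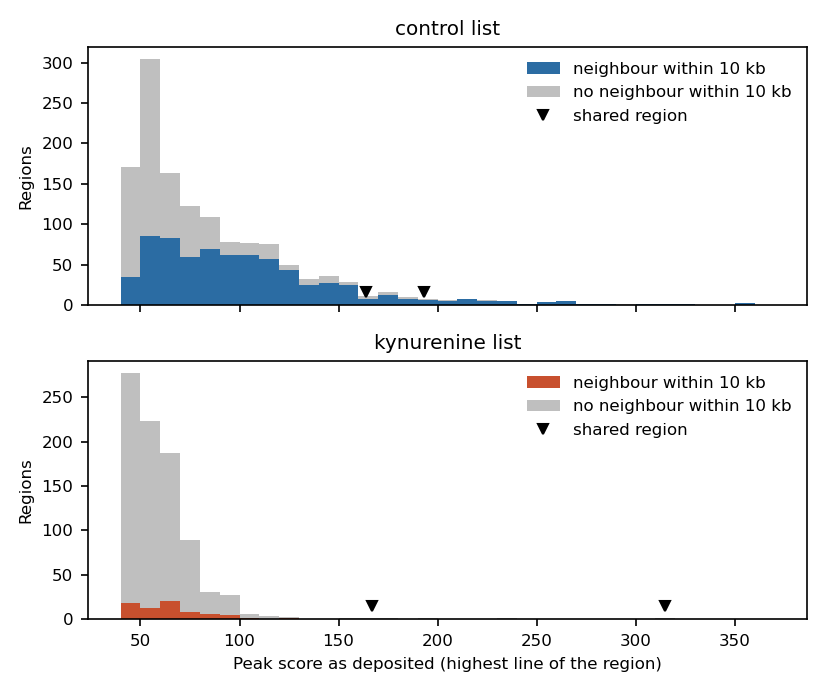
Number of regions by deposited peak score in bins of 10 for the control list (top) and the kynurenine list (bottom), with regions that have a neighbour within 10 kb in colour, the others in grey, and triangles at the scores of the 2 shared regions. Crowded regions fill most of the upper range of the control list, where their median is 92 against 58, and few bins of the kynurenine list.

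The share of regions per chromosome differed between control-only and kynurenine-only regions for 12 of 24 chromosomes (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). Chromosomes 1, 9, 16, 21 and Y held a larger share of the control list. For Y this is a trait of the list and not of binding, since endometrial cells are of female origin. Chromosome 1 carried 15.8% of control-only regions (95% Wilson interval 13.9% to 17.8%) and 7.76% of kynurenine-only regions (6.15% to 9.76%; adjusted p = 5.5e-07, Fisher's exact test). Chromosome 21 carried 9.91% (8.42% to 11.6%) and 4.0% (2.88% to 5.54%; adjusted p = 2.4e-06, Fisher's exact test). Chromosomes 8, 11, 17, 18, 19, 22 and X held a larger share of the kynurenine list, such as 4.24% against 1.58% on chromosome X (adjusted p = 0.00094) and 3.88% against 1.35% on chromosome 18 (adjusted p = 0.00094, both by Fisher's exact test). The shares of a list depend on each other, since a larger control share on some chromosomes lowers it on the others. Chromosome 8 held 52 control-only and 52 kynurenine-only regions. Some of these calls ended under alternatives set beforehand (Fisher's exact test): chromosome 8 without chromosome Y (adjusted p = 0.066), and chromosomes 17, 19 and 22 with lists of equal length (adjusted p = 0.20, 0.11 and 0.25). The lists of equal length were not neutral to crowding. The control list then had 62.9% of regions with a neighbour within 10 kb, against 45.7% when drawn at random to 852 regions. When loci were counted in place of regions, 0 of 24 chromosomes passed the adjusted threshold and 1 passed unadjusted. The difference on chromosome 1 shrank to 9.47% of control and 7.64% of kynurenine loci, while that on chromosome X stayed close in size, at 2.41% and 4.69%, and so did that on chromosome 19, at 0.688% and 1.61% of loci against 0.375% and 1.41% of regions. Outside the dense windows, 0 passed adjusted and 3 unadjusted, and the differences shrank unevenly. The control share minus the kynurenine share was 0.66 percentage points on chromosome 1 (8.0 over all regions) and -0.34 on chromosome 21 (5.91). It was still 2.92 on chromosome 9 (4.16), 1.20 on chromosome Y (1.87), -1.84 on chromosome 18 (-2.53), -0.87 on chromosome 19 (-1.04), -0.85 on chromosome 22 (-1.21) and -1.82 on chromosome X (-2.66). At a score of at least 100, 18 kynurenine regions remained, and the 2 shared ones among them were left out of this comparison. There 0 passed adjusted and 2 unadjusted, and the kynurenine shares rest on few regions. The difference was then 13.3 points on chromosome 1, 10.2 on chromosome 16 (3.44 over all regions), 8.33 on chromosome 21, 5.21 on chromosome Y and -17.4 on chromosome 8 (-2.21), with the sign changed on chromosomes 9, 17, 18, 19 and X.

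The third comparison asked whether kynurenine regions lay close to control regions without overlapping them. Without the 2 overlapping regions, and with overlaps left out of the placements too, 55 kynurenine regions (6.46%) lay within 10 kb of a control region. Random placement gave 5.38 ± 2.31 (SD over 1000 placements), so the observed number was 10.2 times as high (permutation p = 0.0010, one-sided). Within 1 kb there were 6 kynurenine regions against 0.788 ± 0.892 (permutation p = 0.0010), and within 100 kb 131 against 37.1 ± 6.18 (permutation p = 0.0010). When each kynurenine region was moved by at most 500 kb from its own place, 24.96 ± 4.40 lay within 10 kb (permutation p = 0.0010) and 100.4 ± 7.06 within 100 kb (permutation p = 0.0010), which lowered the excess within 100 kb to 1.30 times. The number within 1 kb was then 4.55 ± 2.15, and the difference from 6 did not pass the threshold (permutation p = 0.31). Nor did it pass among regions without a neighbour of their own list within 100 kb, where 5 of 690 kynurenine regions lay within 10 kb of such a control region, against 2.17 ± 1.45 (permutation p = 0.065), and 22 within 100 kb, against 21.8 ± 4.56 (permutation p = 0.50). These p-values of 0.0010 are the smallest that 1000 placements can give.

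**Figure D3:**
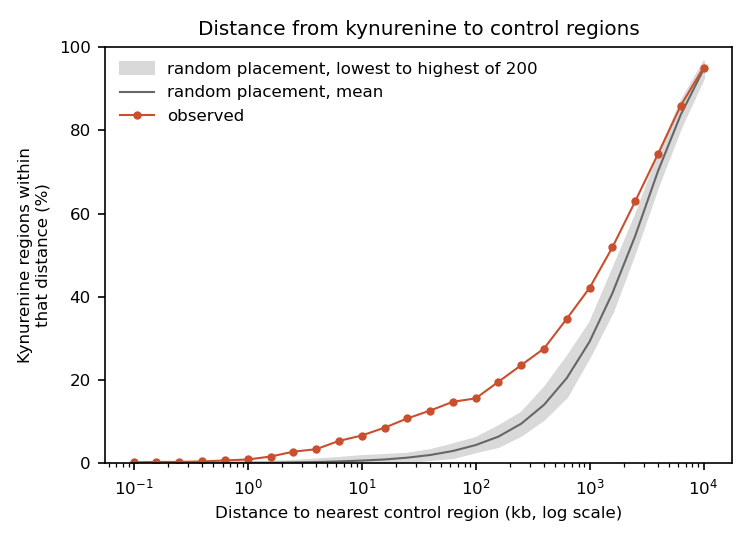
Cumulative percentage of the 852 kynurenine regions (vertical axis) that lie within a given distance of the nearest control region (horizontal axis, kb, log scale), with the 2 overlapping regions included. The red line is the observed percentage, the grey line the mean and the band the range of 200 random placements; at 10 kb the observed value is 6.69% and the mean of the placements 0.673%.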

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

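The alternatives with a score limit, with displacements of at most 500 kb, with isolated regions, loci or dense windows, with random thinning, with midpoints, with neighbours within 1 kb or 100 kb and with deposited lines were chosen after seeing the data. No paired analysis was possible because each list merges replicates A and B, and for the same reason no replicate could be left out. Alternatives that need a q-value, a fold enrichment, repeat masking, transcription start sites, genes or motifs were not run, and of the removal of repeats and extra sequences only that of chromosome Y was. The number of regions fell to 386 in the control list and 18 in the kynurenine list at a score of at least 100, and to 757 in the control list outside dense windows. It stayed within 1.5 times without chromosome Y, at a score of at least 50, with deposited lines and, for the kynurenine list, outside dense windows. Isolated regions numbered 455 in the control list and 690 in the kynurenine list. The 2 shared regions numbered 2 under all alternatives except a gap of 500 bp, which gave 5 control regions. The comparison with chance held in 10 of them. All 10 retain both shared regions, and all except the gap of 500 bp lower the chance number, so they are not independent support. It did not hold under displacements of at most 500 kb (2 against 1.30), 50 kb (2 against 2.79, permutation p = 0.77) and 10 kb (2 against 3.41, permutation p = 0.86). At 50 kb and 10 kb chance exceeded the observed number, and the cause was not tested. Isolated regions alone gave 2 against 0.055 under displacements of at most 500 kb (permutation p = 0.0010, the smallest that 1000 placements can give). With the gap of 500 bp the score difference was 21 in the control list and 76 in the kynurenine list. The difference in crowding lay between 18.8 and 54.7 percentage points under all alternatives run. The number of chromosomes with different shares was 0 at a score of at least 100 (2 unadjusted), 0 outside dense windows and 0 with loci, and 10 to 16 otherwise. At a score of at least 100 only 18 kynurenine regions remained, and the 2 shared ones among them were left out of this comparison. Control minus kynurenine shares changed sign with loci on chromosomes 8 (0.36 points), 11 (0.24), 16 (-0.65) and 21 (-0.14), outside dense windows on chromosome 21 (-0.34), and at a score of at least 100 on chromosomes 9 (-0.52), 17 (3.13), 18 (0.78), 19 (0.26) and X (1.30); the cause was not tested.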

Other observations

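The explanations weighed here were tested after the data were seen, and all tests except the thinning of the control list were chosen after the result itself was seen. Kynurenine regions had a few crowded stretches of their own. On chromosome 10, 8 kynurenine regions lay between 135478666 and 135496407 and no control region lay among them. On chromosome 2, 7 lay between 132918075 and 133030730, and on chromosome 1, 5 lay between 228748399 and 228782273, again without a control region. On chromosome 2, though, 1 control peak number is absent between 132782949 and 133068992, so a removed control peak there is not excluded. Chromosome 21 had 8 kynurenine regions between 11026710 and 11139525, together with 12 control regions.

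Peak numbers were missing from both lists. The highest peak number was 1545 in the control list, with 211 numbers (13.7%) absent, and 941 in the kynurenine list, with 89 (9.46%) absent. They were absent in 34 and 27 runs of consecutive numbers. The longest control run, 43 numbers, fell between 57931655 and 64967525 on chromosome 7. Others were narrowly bounded, with 27 numbers absent between 32492089 and 32575378 on chromosome 16, inside the control locus between 32308606 and 32851580, and 26 between 10556419 and 10886073 on chromosome 21. On chromosome 21 the lists lacked numbers in stretches that met, for example 3 control numbers between 9765597 and 9896794 and 4 kynurenine numbers between 9714463 and 9853301. In all, 10 control runs with 110 of the 211 numbers and 11 kynurenine runs with 50 of the 89 numbers met a run of the other list, so shared peaks among the absent numbers are not excluded. The rule by which these peaks were left out is not given in the sources used here.

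Sharing was limited to 2 regions. Removal of peaks before deposit does not account for most of this. Peak numbers follow position, so a removed control peak lay between the kept peaks around its number, and 55 further kynurenine regions lie in such stretches. Had all of these and all 89 absent kynurenine numbers been shared, 15.5% of the 941 numbered kynurenine peaks would have been. A candidate explanation is that most regions are weak peaks near the calling threshold that a repeat would not call again. In the kynurenine list both shared regions were among the 20 highest scores (Fisher's exact p = 0.00052), while in the control list they ranked 46 and 81 of 1334 and 0 of the 20 highest were shared (Fisher's exact p = 1). With 2 shared regions the control comparison decides nothing, and this stays open. A move of AHR to other sites after kynurenine also stays open, since no list per replicate shows how far replicates of the same treatment overlap.

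Control regions were more crowded than kynurenine regions. The longer control list does not account for it: drawn at random to 852 regions, the control list kept 45.7% with a neighbour within 10 kb (lowest of 1000 draws 40.3%), against 8.45% in the kynurenine list. The control-dense windows may be stretches that give peaks in either treatment, since 19 of the 23 control-dense windows held a kynurenine region, against 6.20 by random placement (highest of 1000 placements 14). This bears on where the windows lie and leaves open the crowding outside them and why the control list has so many more regions in them, for which library depth, input depth and treatment cannot be separated with 1 list per treatment. Whether the sequence of these windows is repeated was not tested.

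Whether the different chromosome shares come from a few crowded stretches was not decided. Of the 5 chromosomes with a larger control share, 0 kept over 50% of the difference when loci were counted in place of regions, but 2 did outside the dense windows, chromosome 9 with 70.1% and chromosome Y with 64.1% left. Of the 7 chromosomes with a larger kynurenine share, 3 kept over 50% with loci and 5 outside the dense windows, among them chromosome X with 85.8% and 68.5%. In both settings 0 of 24 chromosomes passed the adjusted threshold (Fisher's exact test). The percentages left are therefore of differences that these tests do not establish, and they do not argue against crowded stretches. On chromosome 1, 22.8% was left with loci and 8.28% outside the dense windows, and on chromosome 21 the sign changed in both. On chromosome 16, 13.5% was left outside the dense windows, and the sign changed with loci. Most of the difference on chromosomes 1, 16 and 21 therefore lay in crowded stretches. The dense windows were picked by their number of regions, so this describes where the difference lies and not its cause. An effect of kynurenine on the chromosomes that AHR occupies stays open, as untested. Chromosome Y cannot bear on it, because endometrial cells are of female origin.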
